A study of Mus musculus with 15 samples.

How the data were processed

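The series measured polyA RNA in pulverized left liver lobe of male C57Bl/6J mice, a common inbred strain, with 15 libraries in all. Per the labels, 3 diets were given: a base diet with 4% fat (BD), a high-fat diet with 31% fat (HFD), and a diet with 31% fat that lacked methionine, choline and folate (MCD). Each diet had 5 libraries. All 15 libraries carried the same treatment label, the vehicle alone (5% of an emulsifier in saline), and the same time of 24 h after treatment, so no library of a mouse given tetrachloroethylene entered. Replicate numbers were given in order of deposit and pair nothing between diets. The labels do not say that each library came from its own animal, so p-values measure the spread between these samples.

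The deposited files hold whole-number counts of reads per gene symbol, 1 file per library, with 23420 genes and 5 closing rows for reads given to no gene. Per the submitters' processing notes, Trimmomatic, TopHat2 (2.0.13), HTSeq and DESeq2 were used with the genome build GRCm38/mm10, and the libraries were prepared with a kit that keeps strand. The gene annotation, strand setting and counting mode are not given in the sources used here. Overlapping and antisense genes are therefore uncertain. The closing rows stayed out of library sizes and tests. Reads outside genes made up 12.7% to 17.0% of the reads with a unique position, and ambiguous reads 0.567% to 0.841%. Alignments that were not unique numbered 1.15 to 2.80 per gene count, and they entered no gene. Members of families of near-identical genes (Cyp2c, Cyp3a, Gsta, Gstm, Mup, Saa) are therefore known from their unique stretches only, and their values are uncertain. Gene symbols were older ones in part: of 859 listed gene entries 845 were found, 2 of them by an older symbol. None of the 13 protein genes of the mitochondrial genome was among the symbols, so that list was not analysed here.

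Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, genes kept by filterByExpr with the diet (minimum count 10, minimum total 15), which left 12193 genes, 1 quasi-likelihood fit over the 15 libraries with robust estimation, and a two-sided F test for each of the 3 pairs of diets. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over the genes tested), and every adjusted p for a gene below is from this test. Fold changes are on the log2 scale, their SE is the size of the fold change divided by the square root of F, and CPM values are gene counts scaled to a common library size with the TMM factors. The common biological coefficient of variation was 0.176. Depth ran from 3704642 to 23131089 gene counts per library, and 3 counts corresponded to 0.118 to 0.852 CPM, so genes below about 1 CPM are poorly measured in the shallow libraries.

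Before the data were examined, 35 gene lists (13 on xenobiotic, lipid and one-carbon metabolism and on fibrosis and inflammation, and 22 on other cell types, stress, sex-biased, zonal, clock and handling-related genes), the comparisons and the rule for named genes were fixed. Lists with at least 3 tested members (31) were tested with camera from limma 3.58.1 with an inter-gene correlation preset to 0.01, and again with the correlation estimated per list. For neutrophil, pancreatic and erythroid markers, with 1, 1 and 2 tested members, no list test was made. Lists share members: 12 of 23 NRF2 targets and 12 of 36 P450 genes also stand in another list. A list score is the mean over members of log2 CPM (prior count 2) minus the gene's BD mean. Genes named are the 5 largest increases and 5 largest decreases per comparison among called genes with at least 5 CPM in the higher diet and no overlap between diets, the 2 members with the smallest p of each of the 13 lists and the first of each other list past the threshold, 10 enzymes of tetrachloroethylene metabolism, and the genes with the largest change in the same or the opposite direction on both 31% fat diets. Predicted genes were left out of that rule.

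Replicate pairs of the same diet differed far more than sampling noise (chi-square per degree of freedom 6.89 to 61.1 over 30 pairs), so no library was counted as deposited more than once. The procedure was tested on simulated counts with 200 changed genes: of 50 genes changed 1.5-fold, 20 were recovered for HFD vs BD, 20 for MCD vs BD and 24 for MCD vs HFD, and of 50 changed 4-fold 48, 50 and 49. False calls made up 4.76%, 3.17% and 6.77% of the calls. Of 200 random lists per comparison, 8, 11 and 5 had a camera p under 0.05. Genes were drawn independently there, so these counts say nothing of lists with correlated members. In the real lists the estimated correlation reached 0.692. Alternatives covered DESeq2 1.42.0 and limma-voom, other scalings, filters, thresholds and fits, and leaving out each library. Without 2 doubtful libraries, with a covariate for non-unique alignments, and with counts thinned to the shallowest library were added after seeing the data. Positions of genes are from GENCODE M21 on GRCm38, 1-based.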

Results

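Liver RNA of male mice was compared between a base diet, a high-fat diet and a high-fat diet without methionine, choline and folate, with 5 libraries per diet. The series concerns how fatty liver disease alters the fate of tetrachloroethylene, a chlorinated solvent that is oxidised by P450 enzymes or conjugated with glutathione. The libraries held 3704642 to 23131089 gene counts (median 10312311), and 13652 to 16090 genes had at least 1 count. Depth was 11139026 ± 7030891 gene counts for BD, 10960686 ± 6219671 for HFD and 15147187 ± 5782893 for MCD (SD, n = 5). The difference of MCD from BD was within the spread between libraries (two-sided exact permutation p = 0.349, adjusted p = 0.571 over 18 tests). Non-unique alignments per gene count were 1.88 ± 0.525 in BD, 1.89 ± 0.510 in HFD and 1.37 ± 0.183 in MCD (SD, n = 5, exact permutation p = 0.0238 for MCD against BD, adjusted p = 0.286). The first principal component held 37.1% of the variance and ran from BD to MCD, with HFD replicate 2 among the MCD libraries (28.4, against 15.6 to 39.4 for MCD and -12.7 to -0.415 for the other HFD libraries). Over 1232 genes called between MCD and HFD without it, this library lay nearer the MCD mean for 78.9% (MCD libraries, each held out in turn, 64.7% to 94.9%, and the other HFD libraries 5.54% to 38.1%). The BD samples carry numbers at least 66 above those of the other 10 samples, so any batch or day that follows these numbers cannot be told apart from the base diet.

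Some enzymes of tetrachloroethylene metabolism fell strongly on both 31% fat diets, and others were not called. Cyp3a11, an abundant P450 induced through the pregnane X receptor (chromosome 5, 145854426 to 145879964), fell from 6564 ± 346 CPM in BD to 899 ± 282 in HFD (log2 fold change -2.87 ± 0.16 SE, adjusted p = 4.10e-09) and 1509 ± 139 in MCD (log2 fold change -2.12 ± 0.16 SE, adjusted p = 6.01e-08, SD of CPM, n = 5). Cyp2b10, a phenobarbital-inducible P450 (chromosome 7, 25897620 to 25926624), fell from 32.8 ± 15.7 CPM to 0.849 ± 1.27 in HFD (log2 fold change -5.19 ± 0.57 SE, adjusted p = 6.08e-05) and 1.13 ± 0.408 in MCD (log2 fold change -4.80 ± 0.52 SE, adjusted p = 3.95e-05), and HFD replicate 2 had the highest HFD value. Cyp2e1, an oxidative P450 of small solvents (chromosome 7, 140763739 to 140774987), was not called in any pair of diets: it stood at 7323 ± 784 CPM in BD, 7894 ± 1148 in HFD and 7542 ± 1219 in MCD. Its log2 fold changes against BD were 0.11 (95% interval -0.15 to 0.37, adjusted p = 0.699) for HFD and 0.04 (95% interval -0.22 to 0.31, adjusted p = 0.846) for MCD. Between MCD and HFD, Cyp3a11 was higher by 0.75 ± 0.15 (log2, SE, adjusted p = 0.0147), a call that ended without HFD replicate 4 (adjusted p = 0.0509) and with a covariate for non-unique alignments, chosen after seeing the data (adjusted p = 0.0618). The log2 fold change of Cyp2b10 was -5.81 by limma-voom, -6.65 without HFD replicate 2 and -6.65 without HFD replicate 2 and MCD replicate 3 in HFD, and -5.43 with the covariate for non-unique alignments in MCD.

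Among the glutathione steps, Gstt1, a theta class transferase (chromosome 10, 75783813 to 75798584), was not called, at -0.19 (95% interval -0.41 to 0.02, adjusted p = 0.313) in HFD and -0.07 (95% interval -0.29 to 0.14, adjusted p = 0.654) in MCD against BD. Gstp1 (chromosome 19, 4035407 to 4037985), a pi class transferase with near-identical copies, fell by 1.46 ± 0.31 in HFD and by 1.07 ± 0.31 in MCD on the log2 scale (SE, adjusted p = 0.0105 and 0.0229). The MCD call ended without BD replicate 5 or MCD replicate 3 (adjusted p = 0.0563 and 0.0523) and with the covariate for non-unique alignments (adjusted p = 0.107). Nat8, an N-acetyltransferase of mercapturate formation (chromosome 6, 85830388 to 85832082), fell from 21.6 ± 2.36 CPM in BD to 10.1 ± 1.57 in HFD and 12.8 ± 2.57 in MCD (SD, n = 5, edgeR adjusted p = 7.07e-05 and 6.78e-04). Kyat1, a cysteine conjugate beta-lyase listed as Ccbl1 (chromosome 2, 30185124 to 30205847), fell by 0.84 ± 0.16 in MCD and by 0.55 ± 0.16 in HFD (log2, SE, adjusted p = 0.00119 and 0.0444). The HFD call of Ccbl1 ended in turn without BD replicates 1, 2, 3 or 4, HFD replicates 1, 2, 3 or 4 or MCD replicates 2, 4 or 5 (adjusted p = 0.0724, 0.0782, 0.107, 0.117, 0.0829, 0.0862, 0.0677, 0.055, 0.0531, 0.0507 and 0.0615 in turn). It also ended without TMM factors, without a count filter and after thinning (adjusted p = 0.0596, 0.0558 and 0.0622). Kyat3, a related lyase listed as Ccbl2 (chromosome 3, 142701051 to 142746870), was not called against BD, at 0.07 (95% interval -0.19 to 0.32, adjusted p = 0.827) in HFD and 0.05 (95% interval -0.21 to 0.30, adjusted p = 0.816) in MCD. Dpep1, a dipeptidase (chromosome 8, 123186242 to 123201812), had means of 1.47 to 2.05 CPM and was not called against BD, at 0.09 (95% interval -0.47 to 0.66, adjusted p = 0.953) in HFD and 0.45 (95% interval -0.08 to 0.98, adjusted p = 0.228) in MCD. Between MCD and HFD none of Cyp2e1, Cyp2b10, Gstt1, Gstp1, Dpep1, Ccbl1, Ccbl2 and Nat8 was called (edgeR adjusted p 0.179 for Nat8 to 0.959 for Ccbl2). Ggt1 (chromosome 10, 75561604 to 75586200), a gamma-glutamyltransferase, had 5, 6 and 9 counts in all over the BD, HFD and MCD libraries and was not testable at this depth.

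**Figure D1:**
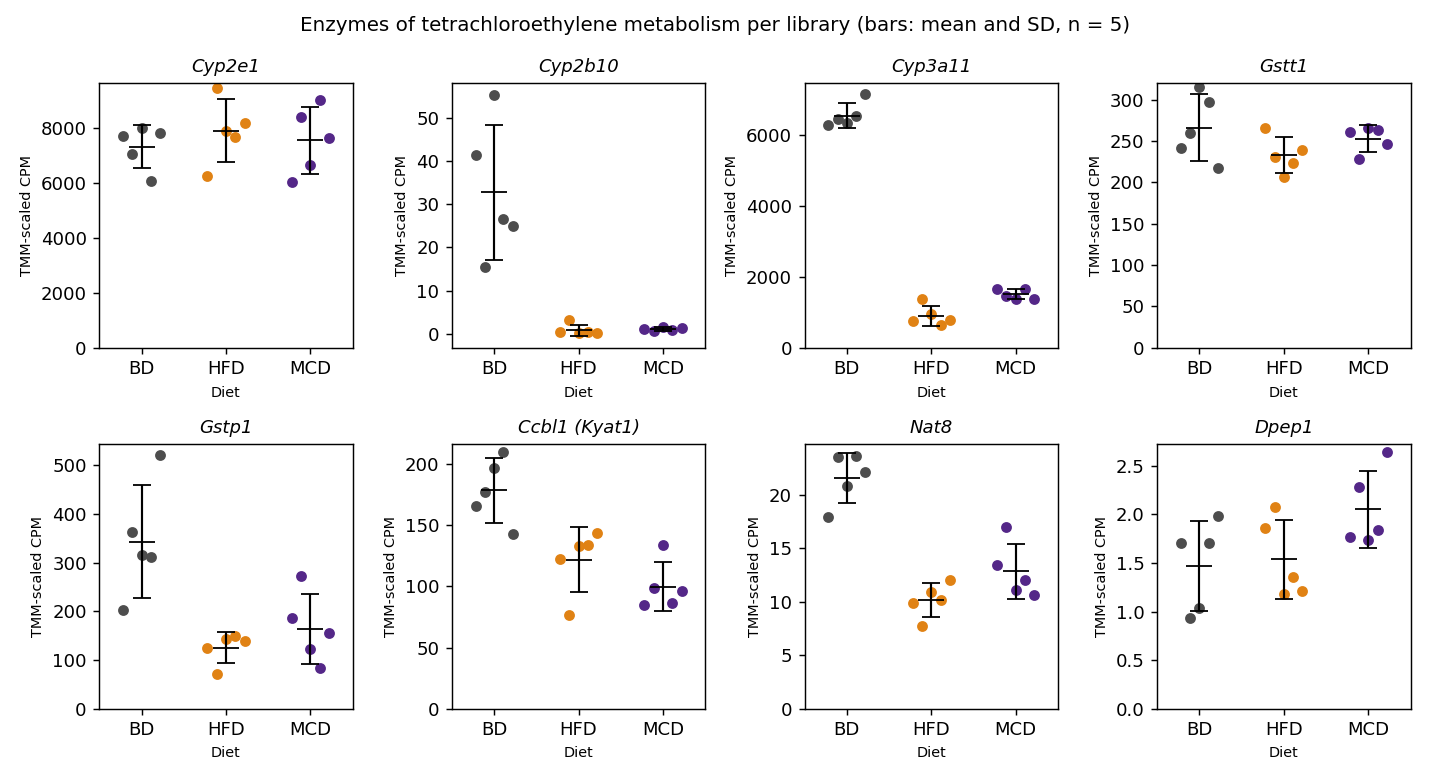
TMM-scaled CPM of 8 tetrachloroethylene-metabolising enzymes in each library, by diet, with the mean and SD of 5 libraries as bars. Cyp2e1 means lie at 7323, 7894 and 7542 CPM in BD, HFD and MCD, whereas Cyp3a11 falls from 6564 CPM in BD to 899 in HFD and 1509 in MCD.

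The comparison of HFD with BD sets 31% against 4% fat. Of the genes tested, 15 of 36 P450 enzymes and 16 of 34 genes of glutathione conjugation fell, while 16 of 38 genes of fatty acid oxidation and 7 of 26 of fatty acid synthesis rose. The list calls of oxidation and synthesis were lost, at adjusted p = 0.0548 and 0.123 with an estimated correlation. Xenobiotic P450 enzymes had 1 of 36 tested members higher and 15 lower (1 and 17 adjusted over the list alone). For P450 enzymes camera gave adjusted p = 4.16e-18, and adjusted p = 3.55e-04 with an estimated correlation. Beside Cyp3a11 and Cyp2b10, Cyp2c55 fell by 2.86 ± 0.17 on the log2 scale (SE, n = 5, adjusted p = 4.98e-09). Glutathione conjugation and mercapturate formation had 0 of 34 tested members higher and 16 lower (0 and 17 adjusted over the list alone). For glutathione conjugation camera gave adjusted p = 4.06e-18, and adjusted p = 0.0107 with an estimated correlation. Gsta4 fell from 75.2 ± 7.33 to 19.4 ± 4.94 CPM and Gsta2 from 20.1 ± 5.85 to 2.76 ± 1.21 (SD, n = 5, adjusted p = 1.51e-06 and 2.57e-06). In all, edgeR called 844 of 12193 genes, 445 higher and 399 lower, of which 305 and 301 had no overlap between the 5 libraries of each diet. Over all genes tested 7.05% had no such overlap, where chance gives 0.794%. The P450 score of HFD replicate 2 was -0.393, against -0.904 to -0.778 in the other 4 HFD libraries.

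Genes of fatty acid oxidation and PPAR alpha, the receptor that fatty acids activate, had 16 of 38 tested members higher and 0 lower (21 and 0 adjusted over the list alone). For fatty acid oxidation camera gave adjusted p = 8.02e-14, and adjusted p = 0.0548 with an estimated correlation. Fgf21, a hormone of the fasted liver, rose by 3.07 ± 0.41 (3.83 without BD replicate 2) and Cpt1a, which admits fatty acids to mitochondria, by 1.04 ± 0.13 (log2, SE, adjusted p = 2.02e-04 and 4.25e-05). Fatty acid and triglyceride synthesis had 7 of 26 tested members higher and 0 lower (9 and 0 adjusted over the list alone). For fatty acid synthesis camera gave adjusted p = 4.40e-11, and adjusted p = 0.123 with an estimated correlation. The desaturases Fads2 and Fads1 rose by 1.53 ± 0.14 and 0.70 ± 0.10 (adjusted p = 2.15e-06 and 1.36e-04). HFD replicate 2 had a synthesis score of 0.208, against 0.653 to 0.917 in the other HFD libraries, and a lipid droplet score of 1.34, against 0.0688 to 0.54. The lipid droplet list had 2 of 20 tested members higher and 0 lower (4 and 0 adjusted over the list alone). For lipid droplet genes camera gave adjusted p = 1.70e-04, and adjusted p = 0.298 with an estimated correlation. Plin2, a droplet coat protein, rose by 1.02 ± 0.11 and Fitm2, a protein of droplet formation, by 0.74 ± 0.17 (adjusted p = 1.16e-05 and 0.0105). Apoa4, an apolipoprotein of triglyceride-rich particles, rose from 115 ± 49.2 to 2077 ± 1426 CPM (log2 fold change 4.17 ± 0.43 SE, adjusted p = 4.20e-05), and Mfsd2a, a carrier of lysophosphatidylcholine, from 8.47 ± 4.48 to 132 ± 48 (log2 fold change 3.94 ± 0.44 SE, adjusted p = 1.04e-04). Cholesterol synthesis and uptake had 0 of 25 tested members higher and 1 lower (0 and 1 adjusted over the list alone). For cholesterol synthesis camera gave adjusted p = 0.23. That list test passed at 0.0167 without BD replicate 5 and 0.0307 without HFD replicate 1. Its called member Insig1, a sterol sensor, fell by 0.66 ± 0.16 (adjusted p = 0.0193), a call that ended without BD replicates 2 or 4 or HFD replicates 2 or 5 (adjusted p = 0.0529, 0.0594, 0.0613 and 0.0503 in turn). Bile acid synthesis had 1 of 19 tested members higher and 4 lower (4 and 6 adjusted over the list alone, and 4 and 4 without TMM factors). For bile acid synthesis camera gave adjusted p = 0.0326, and adjusted p = 0.28 with an estimated correlation. Akr1d1 and Cyp27a1, both enzymes of that pathway, fell (-0.53 ± 0.10 and -0.51 ± 0.10, adjusted p = 0.00283 and 0.00388). This list call ended, at camera adjusted p = 0.0717 without BD replicate 1, 0.0549 without BD replicate 3 and 0.123 without HFD replicate 2, and at adjusted p = 0.119 without HFD replicate 2 and MCD replicate 3 and 0.0686 after thinning. Methionine, choline and folate metabolism had 0 of 40 tested members higher and 15 lower (1 and 16 adjusted over the list alone). For one-carbon genes camera gave adjusted p = 2.09e-06, and adjusted p = 0.0229 with an estimated correlation. Cth, which makes cysteine, fell from 640.2 ± 108 to 225 ± 37.4 CPM and Aldh1l1, a folate dehydrogenase, from 2039 ± 275 to 1119 ± 113 (SD, n = 5, adjusted p = 1.51e-06 and 8.10e-05).

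Genes of monocyte-derived and lipid-associated macrophages had 7 of 23 tested members higher and 0 lower (15 and 0 adjusted over the list alone). For macrophage genes camera gave adjusted p = 2.18e-10, and adjusted p = 0.169 with an estimated correlation. Cd68, a lysosomal macrophage marker, rose from 9.15 ± 1.15 to 17.6 ± 5.03 CPM and Ctss, a lysosomal protease, from 38.7 ± 8.25 to 58.5 ± 11.3 (SD, n = 5, adjusted p = 0.00304 and 0.0128). With 1 library left out, 4 to 11 macrophage genes were called. Beside this group, HFD replicate 2 had a macrophage score of 1.59, against 0.419 to 0.687 in the other 4 HFD libraries. Of the genes of extracellular matrix and stellate cell activation edgeR called 0 of 41 (1 without TMM factors), with 12 higher and 0 lower at an unadjusted p under 0.05, 3 called by DESeq2 and 0 by limma-voom. For matrix genes the list test, upward, gave camera adjusted p = 0.0019, and adjusted p = 0.611 with an estimated correlation. HFD replicate 2 had a matrix score of 0.884, against 0.0275 to 0.238, and the list test gave 0.123 without HFD replicate 2, and 0.243 by fry and 0.0874 without HFD replicate 2 and MCD replicate 3. Reln and Col14a1, matrix proteins with the smallest p of that list, stood at 0.29 ± 0.091 and 0.42 ± 0.14 (SE, adjusted p = 0.0644 and 0.0769), with 0 of 41 called when adjusted over the list alone. Col14a1 was called without BD replicate 5, HFD replicate 4 or MCD replicate 2 (adjusted p = 0.0296, 0.0378 and 0.0462 in turn), and Reln without BD replicate 5 or MCD replicate 2 (adjusted p = 0.0411 and 0.0374 in turn). Cytokines and chemokines had 2 of 27 tested members higher and 2 lower (2 and 2 adjusted over the list alone). For cytokines camera gave adjusted p = 0.162. Ccl6 rose by 0.79 ± 0.16 and Ccl9 changed by -0.92 ± 0.14 (adjusted p = 0.00369 and 2.90e-04). That list test passed at 0.00487 without BD replicate 5 and 0.0488 without HFD replicate 4. Glucuronosyl- and sulfotransferases had 1 of 22 tested members higher and 3 lower (1 and 8 adjusted over the list alone). For transferases camera gave adjusted p = 1.53e-04, and adjusted p = 0.123 with an estimated correlation. Ugt2b35 and Sult1c2 changed by -0.59 ± 0.11 and 1.26 ± 0.25 (adjusted p = 0.00339 and 0.00458). Hepatic drug and bile acid transporters had 3 of 27 tested members higher and 2 lower (8 and 3 adjusted over the list alone, and 7 and 2 without TMM factors). For transporters camera gave adjusted p = 0.201. Slco1a4, an uptake carrier of organic anions, fell from 86.1 ± 10.3 to 26 ± 17 CPM and Slc10a2, a bile acid carrier, rose from 12.7 ± 1.51 to 25.3 ± 5.52 (adjusted p = 0.00227 and 2.26e-04). The transporter list test passed at 0.0483 by fry. Derl3, of the degradation of misfolded proteins, changed by 3.27 ± 0.55, Slc13a2, a dicarboxylate carrier, by -5.18 ± 0.41, and Cyp26a1, which degrades retinoic acid, by -3.47 ± 0.47 (log2, SE, adjusted p = 0.00194, 3.17e-07 and 3.03e-04). Without TMM factors 589 genes were higher and 297 lower, and without HFD replicate 2 and MCD replicate 3, an alternative chosen after seeing the data, 636 genes were called.

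The list of circadian clock genes had 11 of 19 tested members higher and 4 lower (11 and 6 adjusted over the list alone) in HFD against BD. For clock genes camera gave adjusted p = 1.95e-05, and adjusted p = 0.0107 with an estimated correlation. In MCD it had 10 of 19 tested members higher and 6 lower (12 and 6 adjusted over the list alone). For clock genes camera gave adjusted p = 0.011, and adjusted p = 0.119 with an estimated correlation. Dbp, an output factor of the clock, rose from 0.64 ± 0.976 CPM in BD, where it had 34 counts in all, to 26.8 ± 11.7 in HFD and 29.6 ± 7.03 in MCD (SD, n = 5, edgeR adjusted p = 2.60e-05 and 1.67e-05). Its log2 fold change of 5.34 in HFD was 6.00 by limma-voom and 6.69 without BD replicate 2, and that of 5.46 in MCD was 6.19 by limma-voom, 6.82 without BD replicate 2 and 4.84 with the covariate for non-unique alignments. Nr1d2, a repressor of the clock loop, rose by 1.33 ± 0.13 in HFD and 1.52 ± 0.13 in MCD (log2, SE, adjusted p = 2.39e-06 and 3.59e-07). Npas2, an activator, changed by -3.02 ± 0.39 and -3.29 ± 0.38 (adjusted p = 1.18e-04 and 2.93e-05). Between MCD and HFD edgeR called 0 of the 19 clock genes (0 and 0 adjusted over the list alone), with 0 higher and 2 lower at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom. For clock genes camera gave adjusted p = 0.42 there, and the median of 0.01 and mean of -0.03 differ in sign. All BD samples carry numbers apart from those of the other diets.

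**Figure D2:**
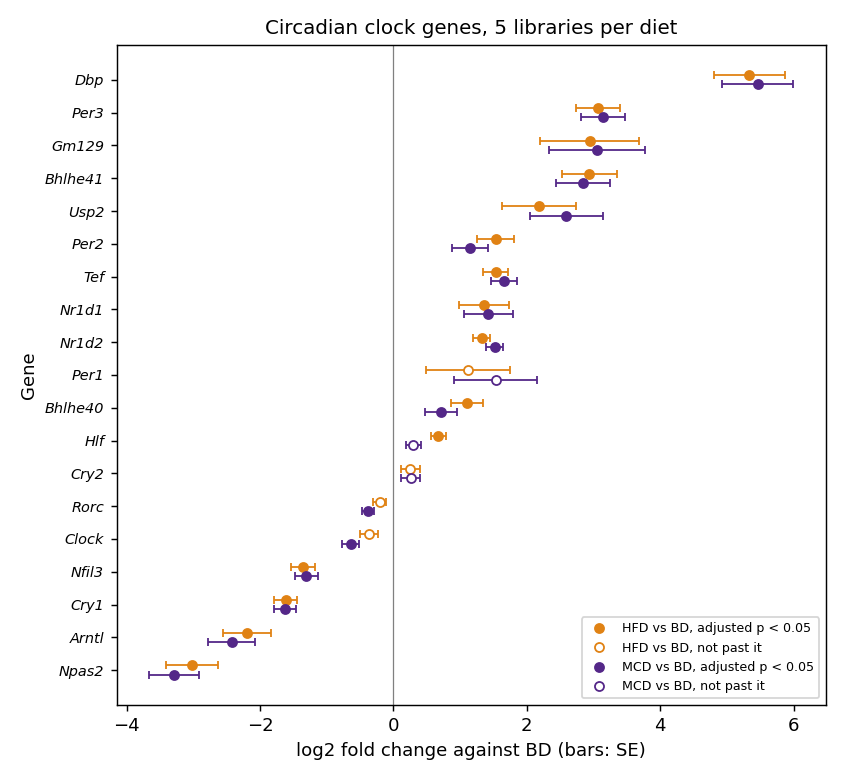
Log2 fold change of the 19 clock genes against BD in HFD and in MCD, with bars for the SE (5 libraries per diet), filled points past an adjusted p of 0.05 and open points not past it. Dbp lies highest at 5.34 in HFD and 5.46 in MCD, and Npas2 lowest at -3.02 and -3.29, and without BD replicate 2 Dbp lies at 6.69 and 6.82.

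The comparison of MCD with BD combines the higher fat with the missing nutrients. Of the genes tested, 23 of 23 macrophage, 35 of 41 matrix and 24 of 30 cell cycle genes rose, and 19 of 36 P450 and 9 of 19 bile acid synthesis genes fell. Without TMM factors bile acid synthesis had 3 members higher and 3 lower, with 1 library left out 4 to 9 were called, and with a covariate for non-unique alignments 5. After thinning 12 cell cycle genes were called. The list calls of matrix and bile acid synthesis were lost, at adjusted p = 0.108 and 0.121 with an estimated correlation. Macrophage genes had 23 of 23 tested members higher and 0 lower (23 and 0 adjusted over the list alone). For macrophage genes camera gave adjusted p = 5.64e-23, and adjusted p = 0.0385 with an estimated correlation. Gpnmb, a lysosomal protein of lipid-laden macrophages, rose from 0.187 ± 0.229 CPM, with 13 counts in all over the BD libraries, to 15.7 ± 8.82 CPM (log2 fold change 5.96 ± 1.18 SE, adjusted p = 0.003, log2 fold change 4.01 with the covariate for non-unique alignments and 6.83 after thinning, SD of CPM, n = 5). Genes of extracellular matrix and stellate cells had 35 of 41 tested members higher and 0 lower (36 and 0 adjusted over the list alone). For matrix genes camera gave adjusted p = 2.89e-23, and adjusted p = 0.108 with an estimated correlation. The collagen Col14a1 and the crosslinking enzyme Loxl2 rose by 1.08 ± 0.14 and 1.40 ± 0.19 (log2, SE, adjusted p = 3.95e-05 and 5.98e-05). The cell cycle list had 24 of 30 tested members higher and 0 lower (27 and 0 adjusted over the list alone). For cell cycle genes camera gave adjusted p = 2.62e-26, and adjusted p = 0.00687 with an estimated correlation. Ccnd1, cyclin D1, rose from 19.8 ± 2.47 to 120.1 ± 17.6 CPM (SD, n = 5, adjusted p = 1.89e-10). In all, edgeR called 2610 of 12193 genes, 1557 higher and 1053 lower, and 1069 and 634 of them had no overlap between diets (15.4% of all genes tested, against 0.794% by chance). MCD replicate 3 had the lowest macrophage score of its diet, 1.21 against 1.72 to 1.96, and BD replicate 5 the highest of its own, 0.411 against -0.237 to -0.0109. Cd68 rose to 23.8 ± 5.05 CPM and Ctss to 90.3 ± 5.75 (SD, n = 5, adjusted p = 5.31e-05 and 1.41e-05), and Mmp12, a macrophage elastase, from 0.317 ± 0.162 to 17.6 ± 8.98 CPM (log2 fold change 5.60 ± 1.33 SE, adjusted p = 0.00948, log2 fold change 3.61 with the covariate for non-unique alignments). Cytokines and chemokines had 15 of 27 tested members higher and 2 lower (17 and 2 adjusted over the list alone). For cytokines camera gave adjusted p = 1.42e-06, and adjusted p = 0.131 with an estimated correlation. Ccl6 and the adhesion molecule Vcam1 rose by 1.34 ± 0.15 and 1.79 ± 0.24 (adjusted p = 1.41e-05 and 1.24e-04).

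Xenobiotic P450 enzymes had 3 of 36 tested members higher and 19 lower (4 and 21 adjusted over the list alone). For P450 enzymes camera gave adjusted p = 3.88e-14, and adjusted p = 0.00136 with an estimated correlation. Cyp2c29 fell from 2944 ± 320.4 to 614 ± 122 CPM and Cyp2c55 from 23.1 ± 2.13 to 3.31 ± 0.923 (SD, n = 5, adjusted p = 4.97e-09 and 3.97e-09). Cyp2b9, a female-biased P450, rose from 0.647 ± 0.453 to 44.9 ± 45.5 CPM (log2 fold change 6.40 ± 1.79 SE, adjusted p = 0.0229, log2 fold change 5.78 without MCD replicate 4 and 3.28 with the covariate for non-unique alignments), a call that ended without BD replicates 2 or 5 (adjusted p = 0.0543 and 0.0544 in turn) and with the covariate for non-unique alignments (adjusted p = 0.0803). Glutathione conjugation had 4 of 34 tested members higher and 11 lower (4 and 13 adjusted over the list alone). For glutathione conjugation camera gave adjusted p = 0.00531, and adjusted p = 0.336 with an estimated correlation. Gstt3, a theta class transferase, and Ggt6 fell, the latter by 1.14 ± 0.17 (adjusted p = 1.31e-04 and 1.72e-04). Glucuronosyl- and sulfotransferases had 1 of 22 tested members higher and 7 lower (1 and 7 adjusted over the list alone, and 2 and 4 without TMM factors). For transferases camera gave adjusted p = 0.0134, and adjusted p = 0.254 with an estimated correlation. Ugt2a3 changed by -0.66 ± 0.11 and Sult1c2 changed by 1.99 ± 0.25 (adjusted p = 5.08e-04 and 3.95e-05). That list test gave 0.0585 without BD replicate 5. Transporters had 6 of 27 tested members higher and 4 lower (8 and 5 adjusted over the list alone, and 9 and 3 without TMM factors), a list whose median of -0.15 and mean of 0.01 differ in sign. For transporters camera gave adjusted p = 0.91. The prostaglandin carrier Slco2a1 changed by -1.25 ± 0.20 and Slc10a2 by 0.76 ± 0.14 (adjusted p = 4.20e-04 and 6.47e-04). Methionine, choline and folate metabolism had 4 of 40 tested members higher and 19 lower (5 and 21 adjusted over the list alone, and 7 and 17 without TMM factors). For one-carbon genes camera gave adjusted p = 1.46e-06, and adjusted p = 0.0261 with an estimated correlation. Cth fell to 225 ± 32.6 and Aldh1l1 to 911 ± 113 CPM (SD, n = 5, adjusted p = 1.35e-06 and 3.21e-06). Bile acid synthesis had 0 of 19 tested members higher and 9 lower (1 and 10 adjusted over the list alone, and 3 and 3 without TMM factors). For bile acid synthesis camera gave adjusted p = 0.00106, and adjusted p = 0.121 with an estimated correlation. Cyp27a1 and Akr1d1 changed by -0.75 ± 0.10 and -0.67 ± 0.10 (adjusted p = 7.09e-05 and 1.72e-04). Cholesterol synthesis had 0 of 25 tested members higher and 8 lower (0 and 10 adjusted over the list alone, and 0 and 3 without TMM factors). For cholesterol synthesis camera gave adjusted p = 1.69e-04, and adjusted p = 0.414 with an estimated correlation. The sterol enzymes Tm7sf2 and Ebp changed by -0.91 ± 0.16 and -0.61 ± 0.13 (adjusted p = 5.99e-04 and 0.00184).

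Lipid droplet genes had 10 of 20 tested members higher and 0 lower (12 and 0 adjusted over the list alone). For lipid droplet genes camera gave adjusted p = 1.45e-05, and adjusted p = 0.2 with an estimated correlation. The coat proteins Plin4 and Plin2 rose by 2.66 ± 0.53 (1.82 with the covariate for non-unique alignments) and 0.87 ± 0.11 (log2, SE, adjusted p = 0.00313 and 4.72e-05). Fatty acid oxidation and PPAR alpha targets had 19 of 38 tested members higher and 0 lower (21 and 0 adjusted over the list alone). For fatty acid oxidation camera gave adjusted p = 1.22e-07, and adjusted p = 0.15 with an estimated correlation. Vnn1, a pantetheinase, rose by 1.93 ± 0.25 and Fgf21 by 2.74 ± 0.40 (3.50 without BD replicate 2) (adjusted p = 9.94e-05 and 2.26e-04). Fatty acid synthesis had 7 of 26 tested members higher and 3 lower (7 and 3 adjusted over the list alone). For fatty acid synthesis camera gave adjusted p = 0.308. Fads2 and the pyruvate kinase Pklr rose by 1.05 ± 0.14 and 0.99 ± 0.18 (adjusted p = 7.09e-05 and 8.15e-04). That list test passed at 0.0309 without BD replicate 4. Plasma proteins of hepatocytes had 0 of 28 tested members higher and 14 lower (0 and 19 adjusted over the list alone, and 1 and 9 without TMM factors). For plasma proteins camera gave adjusted p = 1.98e-06, and adjusted p = 0.161 with an estimated correlation. Serpinc1, antithrombin, changed by -0.47 ± 0.078 (adjusted p = 3.26e-04). Ly6d, a surface protein, rose from 0.746 ± 0.302 to 25.2 ± 13.8 CPM (SD, n = 5, log2 fold change 5.07, and 2.91 with the covariate for non-unique alignments), while Slc13a2 changed by -5.31 ± 0.39, Srgap3 by -3.24 ± 0.31 and Cyp26a1 by -3.16 ± 0.45 (log2, SE, adjusted p = 0.0094, 6.01e-08, 3.35e-06 and 2.00e-04). Without TMM factors the median of all genes moved from -0.03 to 0.12 on the log2 scale, with 2308 genes higher and 512 lower, and without HFD replicate 2 and MCD replicate 3 2772 genes were called.

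**Figure D3:**
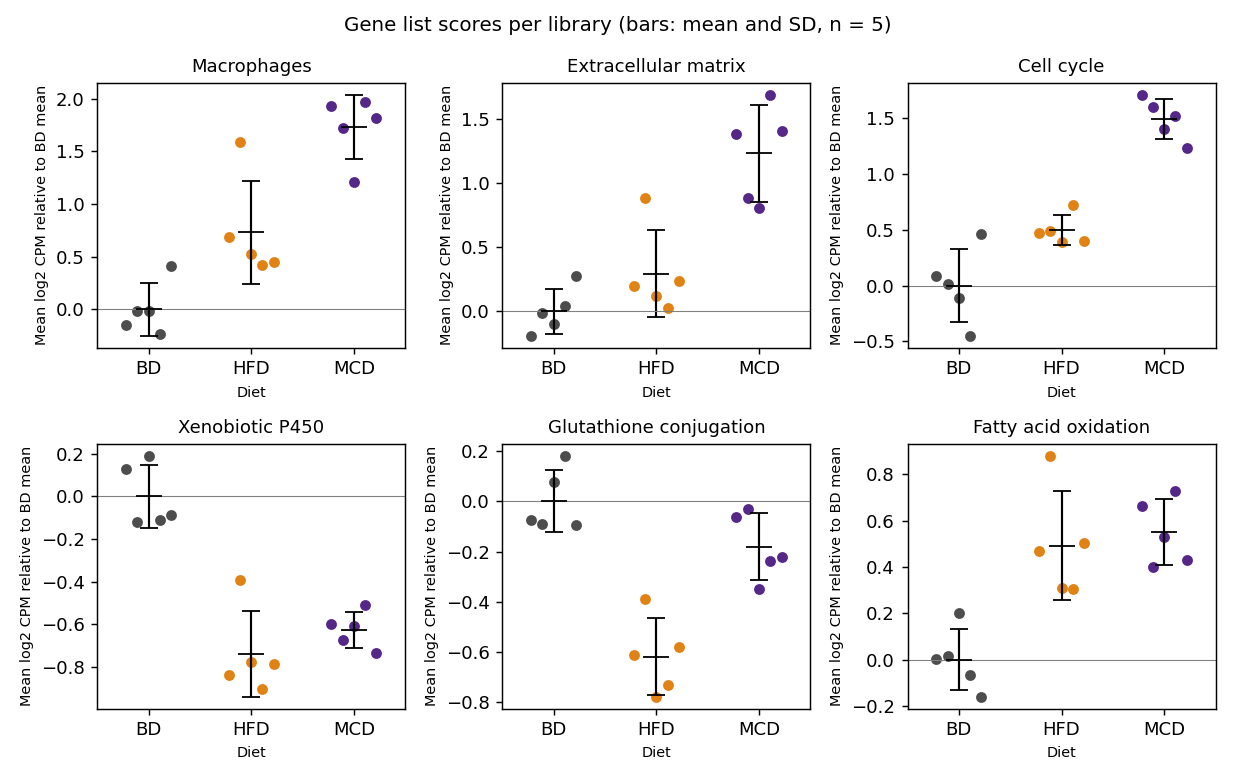
Mean log2 CPM of 6 gene lists in each library relative to the BD mean, by diet, with the mean and SD of 5 libraries as bars. Cell cycle scores lie at 1.24 to 1.71 in MCD and at 0.394 to 0.722 in HFD, whereas the macrophage score of HFD replicate 2 (1.59) lies within the MCD range of 1.21 to 1.96.

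The comparison of MCD with HFD sets side by side diets of the same fat content that differ, per the labels, in methionine, choline and folate. Of the genes tested, 19 of 30 cell cycle, 23 of 41 matrix and 6 of 34 glutathione conjugation genes were higher in MCD. With 1 library left out these counts ranged over 11 to 20, 6 to 31 and 3 to 13, and with a covariate for non-unique alignments 4 matrix and 3 glutathione conjugation genes were called. In the fit of these 2 diets alone 12 matrix genes were called, and after thinning 10 cell cycle genes. The list calls of matrix and glutathione conjugation were lost, at adjusted p = 0.106 and 0.106 with an estimated correlation. The cell cycle list had 19 of 30 tested members higher and 0 lower (23 and 0 adjusted over the list alone). For cell cycle genes camera gave adjusted p = 3.50e-28, and adjusted p = 0.019 with an estimated correlation. Mki67, a proliferation marker, rose from 3.51 ± 1.16 CPM in HFD to 9.6 ± 1.56 in MCD (log2 fold change 1.51 ± 0.29 SE, adjusted p = 0.0119, SD of CPM, n = 5) and Cdc20, an activator of mitotic exit, from 0.663 ± 0.279 to 3.67 ± 1.54 (log2 fold change 2.33 ± 0.35 SE, adjusted p = 0.00314). Matrix genes had 23 of 41 tested members higher and 0 lower (33 and 0 adjusted over the list alone). For matrix genes camera gave adjusted p = 5.45e-30, and adjusted p = 0.106 with an estimated correlation. Sparc, a collagen-binding protein, rose from 71.5 ± 13.2 to 156 ± 37 CPM and the stellate cell receptor Pdgfrb from 15.1 ± 3.31 to 27.2 ± 5.3 (SD, n = 5, adjusted p = 0.00395 and 0.00739). Glutathione conjugation had 6 of 34 tested members higher and 0 lower (10 and 0 adjusted over the list alone). For glutathione conjugation camera gave adjusted p = 2.75e-08, and adjusted p = 0.106 with an estimated correlation. The transferases Gsta2, Gsta4 and Gstm3 rose by 1.86 ± 0.26, 1.40 ± 0.17 and 1.52 ± 0.27 (log2, SE, adjusted p = 0.00278, 0.00119 and 0.0119). In all, edgeR called 384 of 12193 genes, 271 higher and 113 lower (411 and 67 without TMM factors), of which 162 and 61 had no overlap between diets (4.32% of all genes tested, against 0.794% by chance). Beside these groups, HFD replicate 2 scored 0.49 for the cell cycle (0.394 to 0.722 in the other HFD libraries), 0.884 for the matrix (0.0275 to 0.238) and -0.389 for glutathione conjugation (-0.779 to -0.581). The count of 384 moved to 181 without HFD replicate 1, to 1248 without HFD replicate 2, to 156, 74 and 155 without HFD replicates 3, 4 and 5, and to 113, 142 and 220 without MCD replicates 1, 4 and 5. It was 1365 without both HFD replicate 2 and MCD replicate 3, 711 by DESeq2 and 224 in a fit of these 2 diets alone. With the covariate 82 genes were called, and after thinning 176.

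Macrophage genes had 6 of 23 tested members higher and 0 lower (18 and 0 adjusted over the list alone). For macrophage genes camera gave adjusted p = 1.79e-14, and adjusted p = 0.106 with an estimated correlation. Cx3cr1 and Itgax, markers of recruited cells, rose by 2.07 ± 0.39 and 1.81 ± 0.36 (2.52 without HFD replicate 2 and MCD replicate 3) (log2, SE, adjusted p = 0.0124 and 0.016). HFD replicate 2 scored 1.59, against 0.419 to 0.687 in the other HFD libraries. With 1 library left out 0 to 18 macrophage genes were called, most without HFD replicate 2, with the covariate 0, and by DESeq2 and limma-voom 10 each. Cytokines had 4 of 27 tested members higher and 0 lower (10 and 0 adjusted over the list alone). For cytokines camera gave adjusted p = 1.95e-08, and adjusted p = 0.127 with an estimated correlation. The chemokines Cxcl10 and Ccl5 rose by 1.44 ± 0.35 (2.04 without HFD replicate 2 and MCD replicate 3) and 1.77 ± 0.46 (adjusted p = 0.0371 and 0.044). Mat2a, which makes S-adenosylmethionine, rose from 84.5 ± 12.7 to 139 ± 15.5 CPM, and Shmt1, a folate enzyme, changed by -0.41 ± 0.11 (adjusted p = 0.00575 and 0.045). Their list of one-carbon genes had 1 of 40 tested members higher and 2 lower (1 and 4 adjusted over the list alone, and 1 and 0 without TMM factors) and passed the threshold at 0.0248 without MCD replicate 2. For one-carbon genes camera gave adjusted p = 0.0836. Fatty acid synthesis had 0 of 26 tested members higher and 2 lower (0 and 15 adjusted over the list alone, and 0 and 0 without TMM factors). For fatty acid synthesis camera gave adjusted p = 9.85e-09, and adjusted p = 0.225 with an estimated correlation. Fads1 and the acyltransferase Agpat2 changed by -0.40 ± 0.10 and -0.42 ± 0.11 (adjusted p = 0.03 and 0.0462). HFD replicate 2 scored 0.208, against 0.653 to 0.917. Cholesterol synthesis had 0 of 25 tested members higher and 1 lower (0 and 3 adjusted over the list alone, and 0 and 0 without TMM factors). For cholesterol synthesis camera gave adjusted p = 4.21e-05, and adjusted p = 0.398 with an estimated correlation. Stard4, a sterol carrier, changed by -0.52 ± 0.13 (adjusted p = 0.0371). That list test gave 0.172 by fry. P450 enzymes had 1 of 36 tested members higher and 4 lower (2 and 5 adjusted over the list alone). For P450 enzymes camera gave adjusted p = 0.233. Cyp2c29 changed by -0.66 ± 0.13 (adjusted p = 0.0157), and the list's median of -0.01 was above 0 without TMM factors. Transporters had 0 of 27 tested members higher and 3 lower (0 and 4 adjusted over the list alone). For transporters camera gave adjusted p = 0.0938. The sterol exporter Abca1 and the cation carrier Slc22a3 changed by -0.59 ± 0.13 and -0.78 ± 0.19 (adjusted p = 0.0216 and 0.0329). Lipid droplet genes had 1 of 20 tested members higher and 0 lower (2 and 0 adjusted over the list alone, and 2 and 0 without TMM factors). For lipid droplet genes camera gave adjusted p = 0.0415, and adjusted p = 0.532 with an estimated correlation. Lpl, lipoprotein lipase, rose by 0.99 ± 0.25 (adjusted p = 0.0443). That list test gave 0.0543 without BD replicate 1, 0.0555 without BD replicate 2, 0.0526 without HFD replicate 1, 0.139 without HFD replicate 3, 0.14 without HFD replicate 4, 0.115 without HFD replicate 5, 0.0832 without MCD replicate 1 and 0.0731 without MCD replicate 4, and 0.248 by fry, and its direction turned with the covariate for non-unique alignments (adjusted p = 0.944). Bile acid synthesis held 0 members called by edgeR of 19 (0 and 0 adjusted over the list alone), with 0 higher and 4 lower at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom. For bile acid synthesis the list test gave camera adjusted p = 0.0239, and adjusted p = 0.249 with an estimated correlation. That list test gave 0.0561 without MCD replicate 1, 0.0634 without MCD replicate 4 and 0.175 with the covariate. Of 38 genes of fatty acid oxidation edgeR called 0 (0 and 0 adjusted over the list alone, camera adjusted p = 0.687, and 0.0455 with the covariate for non-unique alignments), with 1 higher and 3 lower at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by limma-voom. Of 22 transferases it called 0 (0 and 0 adjusted over the list alone, camera adjusted p = 0.63), with 4 higher and 1 lower at an unadjusted p under 0.05, 1 called by DESeq2 and 1 by limma-voom. In both of these lists the median (-0.02 and 0.05) and the mean (0.02 and -0.06) differ in sign, and the median of fatty acid oxidation changed sign without TMM factors. The serpin Serpinb1a and Pcp4l1 rose by 1.67 ± 0.37 (2.28 without HFD replicate 2 and MCD replicate 3) and 1.59 ± 0.22 (adjusted p = 0.0224 and 0.00239). Derl3 fell by 2.27 (log2 fold change -1.31 with the covariate for non-unique alignments, adjusted p = 0.145), the steroid enzyme Cyp17a1 by 1.73, Acpp by 1.51, Srgap3 by 1.47 and Slc41a2 by 1.13 on the log2 scale (adjusted p = 0.0223, 0.0135, 0.00276, 0.0196 and 0.0332). Of the 38 genes that are named in any part and were called in this comparison, calls ended for 5, 5, 3, 1, 12, 15, 23, 14, 17, 6, 2, 17 and 13 in turn without BD replicates 1, 2, 3 and 4, HFD replicates 1, 3, 4 and 5 and MCD replicates 1, 2, 3, 4 and 5 (adjusted p 0.0503 to 0.156). Calls also ended for 25 (adjusted p 0.0544 to 0.174) of them with the covariate for non-unique alignments, 11 (adjusted p 0.0506 to 0.0833) in the fit of these 2 diets alone and 11 (adjusted p 0.0575 to 0.132) after thinning. Without a count filter they ended for 7 (adjusted p 0.0515 to 0.0662), without TMM factors for 5 (adjusted p 0.052 to 0.0888), and by limma-voom for 1 (adjusted p 0.0526).

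The calls on both 31% fat diets against BD overlapped: 348 genes were higher in both and 316 lower in both, where independent lists would share 56.8 and 34.5, and 1 gene, Pcp4l1, was called in opposite directions. The shared genes with the largest change were Dbp, Slc13a2, Cyp2b10, Mfsd2a and Stap1, the last an adaptor protein rising from 0.366 ± 0.199 CPM to 4.79 ± 0.795 in HFD (log2 fold change 3.78 ± 0.26 SE, and 3.14 after thinning) and 6.29 ± 0.747 in MCD (SD, n = 5). Pcp4l1 stood at 7.22 ± 1.75 CPM in BD, 3.83 ± 0.787 in HFD and 11.7 ± 3.45 in MCD (SD, n = 5). Its call in MCD against BD ended without BD replicates 1 or 2 or MCD replicate 4 (adjusted p = 0.0554, 0.0745 and 0.0962 in turn), by limma-voom (adjusted p = 0.0517) and with the covariate for non-unique alignments (adjusted p = 0.123). Its call in HFD ended after thinning (adjusted p = 0.0875). Across genes, which are not independent replicates, the fold changes had a correlation of 0.754 and a covariance of 0.185. Unchanged groups simulated against shared BD libraries gave at most 1 call per diet in each of 20 runs, so their 0 shared calls say nothing of the overlap. Their medians were 0.525 for the correlation and 0.0248 for the covariance, 0.161 below the observed one. With the BD libraries split in 2 and 3 between the comparisons, 159 to 351 genes were shared in the same direction over 20 assignments (median 249). The median correlation was 0.601 and covariance 0.171. A batch or hour common to all BD libraries would enter both parts, so the split cannot tell it from a diet effect. Without BD replicate 3 the 664 genes shared in the same direction numbered 426.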

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

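The tests of explanations in this part were chosen after the result was seen. The search for outlying libraries covered the genes named, among them Csf3r, Cela1, Alas2 and Bpgm, which were chosen after their values were seen. In each diet, a library was singled out when its gap to the nearest other library, divided by the range of the 5, exceeded 0.71 (Dixon's criterion). This held in 32 of 411 groups of 5 values (the log2 CPM of the genes named, the list scores and measures of library quality), and chance alone singles out about 1 in 20. The ratio is given in parentheses. HFD replicate 2 was highest for Cpt1a (0.774), Cyp2b10 (0.718), Cyp2b9 (0.796), Slco1a4 (0.723) and Vnn1 (0.773). It was highest for the P450 (0.754), matrix (0.754) and macrophage (0.771) scores. It was lowest for Acpp (0.769), Ccbl1 (0.746), Cela1 (0.749), Ebp (0.748), Gstp1 (0.766), Hal (0.71) and Stard4 (0.892). BD replicate 2 was lowest for Cyp27a1 (0.751). BD replicate 4 was lowest for Cpt1a (0.771). BD replicate 5 was highest for Sparc (0.739), non-unique alignments per gene count (0.746) and the share of ambiguous reads (0.726), and lowest for Fads2 (0.763), Psat1 (0.856) and Slco2a1 (0.728). HFD replicate 3 was highest for Fgf21 (0.753). HFD replicate 4 was highest for the transporter score (0.716). MCD replicate 2 was highest for Alas2 (0.763) and Ugt2a3 (0.902), and lowest for Apoa4 (0.97). MCD replicate 3 was lowest for Ctss (0.794) and Lpl (0.813). MCD replicate 4 was highest for Stap1 (0.763) and the pericentral hepatocyte genes score (0.755).

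HFD replicate 2 lay among the MCD libraries on the first principal component, in its macrophage and matrix scores and in its fatty acid synthesis score (0.208, with -0.0478 to 0.411 in MCD and 0.653 to 0.917 in the other HFD libraries), while its P450 score was -0.393 (-0.736 to -0.511 and -0.904 to -0.778). An MCD library under the wrong label stays open and cannot be told apart: a cell cycle score of 0.490 lies below the MCD range of 1.24 to 1.71, but the library lay nearer the MCD mean for 78.9% of 1232 genes called between MCD and HFD without it, inside the range of MCD libraries held out in turn (64.7% to 94.9%, other HFD libraries 5.54% to 38.1%). An exchange would leave 1 MCD library among the HFD libraries by that measure, but the lowest MCD value, 64.7% (replicate 3), lay above them. It stays open, as exchanging HFD replicate 2 for MCD replicate 3 gave 887 called genes against the real 384. RNA of these MCD livers mixed into the library would move cell cycle, macrophage and matrix genes alike, but the median share of the distance from the other HFD libraries to MCD was -0.0518 for cell cycle genes, 0.763 for macrophage genes and 0.463 for matrix genes, which argues against mixing. With the effect of non-unique alignments removed by a covariate, its macrophage score was 1.34, against 0.467 to 0.657 in the other HFD libraries, which argues against that measure as the whole cause, and no biological explanation was tested.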

How the results depend on the processing

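Leaving out HFD replicate 2 and MCD replicate 3, the covariate and thinning were chosen after seeing the data, the other alternatives before. No called gene that is named reversed under any alternative: calls were kept in 1548 cases (45 lost, 59 genes) for HFD vs BD, 2173 cases (66 lost, 83 genes) for MCD vs BD and 831 cases (193 lost, 38 genes) for MCD vs HFD. At an adjusted p under 0.01 the counts were 376, 1446 and 43, and with an absolute log2 fold change of at least 1 they were 235, 799 and 156, since both rules are stricter. For MCD vs HFD the count was 711 by DESeq2, 224 in the fit of these 2 diets alone, 1365 without the libraries HFD 2 and MCD 3, 82 with the covariate and 176 after thinning, where fewer counts remained; the cause was not tested for the others. With 1 library left out, the counts ranged from 569 to 974, 1938 to 2809 and 74 to 1248, and the overlap from 426 to 757. The overlap was 276 at an adjusted p under 0.01, 156 with the fold rule and 249 with BD libraries split. Lists past the threshold numbered 5, 5 and 1 with an estimated correlation, and with 1 library left out 16 to 20, 19 to 22 and 14 to 17. List tests past the threshold stayed past it in the same direction in 333, 381 and 284 cases and fell short of it in 27, 19 and 34, others passed in 8, 9 and 5, and 2 turned, lipid droplet genes (adjusted p = 0.944) and male-biased genes (adjusted p = 0.625) with the covariate in MCD vs HFD, for which the cause was not tested. DESeq2 size factors, a library size without the 20 most abundant genes, no count filter, a minimum CPM of 1, no robust estimation and limma-voom left each count of genes within 1.5 times. No paired analysis was possible because the diets share no sample numbers. At the lowest depth, 3 counts correspond to 0.852 CPM, which limits what can be said of genes below about 1 CPM.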

Other observations

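The tests of explanations and of other splits in this part were chosen after the results were seen, and the gene lists before the data were examined. Periportal hepatocyte genes had 0 of 21 members higher and 11 lower in HFD, 1 and 12 in MCD, and 2 and 1 between MCD and HFD. Adjusted over the list alone, 2 and 12, 2 and 13, and 3 and 2 periportal genes were called. Without TMM factors 2 and 12 were called in MCD. For periportal genes camera gave adjusted p = 1.96e-14, 1.84e-09 and 0.685, and adjusted p = 0.00154, 0.00687 and 0.81 with an estimated correlation. Between MCD and HFD the median and mean of this list differ in sign. Agxt2l1, a phospholyase, fell by 1.60 ± 0.15 in HFD (log2, SE, edgeR adjusted p = 1.51e-06) and Hal, which degrades histidine, fell by 1.65 ± 0.13 in MCD (adjusted p = 1.15e-07). Pericentral hepatocyte genes had 5 of 22 members higher and 3 lower in HFD, 4 and 4 in MCD, and 0 and 1 between MCD and HFD. The pericentral genes called when adjusted over the list alone numbered 7 and 5, 4 and 5, and 0 and 1. Without TMM factors pericentral genes numbered 6 higher and 2 lower in MCD and 0 higher and 0 lower between MCD and HFD. For pericentral genes camera gave adjusted p = 0.997, 0.781 and 0.644, and adjusted p = 0.998, 0.875 and 0.81 with an estimated correlation. Their median and mean were of opposite sign in HFD, and the median changed sign without TMM factors in MCD and between MCD and HFD. In HFD the cell cycle list had 2 of 30 tested members higher and 0 lower (2 and 0 adjusted over the list alone). For cell cycle genes camera gave adjusted p = 6.46e-06, and adjusted p = 0.184 with an estimated correlation. Ccnd1 rose by 1.94 ± 0.12 (adjusted p = 7.20e-09). Kupffer cell markers had 1 of 11 members higher and 0 lower in HFD, 8 and 0 in MCD, and 0 and 0 between MCD and HFD. The Kupffer markers called when adjusted over the list alone numbered 1 and 0, 8 and 0, and 0 and 0. Without TMM factors Kupffer markers numbered 2 higher and 0 lower in HFD. For Kupffer markers camera gave adjusted p = 5.98e-04, 1.06e-04 and 0.0879, and adjusted p = 0.269, 0.169 and 0.532 with an estimated correlation. Cd5l, a secreted macrophage protein, rose by 0.66 ± 0.15 in HFD and 0.95 ± 0.15 in MCD (adjusted p = 0.0091 and 2.00e-04). The 0 Kupffer markers called by edgeR between MCD and HFD compare with 1 higher and 0 lower at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by limma-voom, and that list test passed at 0.0288 without MCD replicate 4, and at 0.00399 with the covariate for non-unique alignments. Sinusoidal endothelial markers had 0 of 17 members higher and 0 lower in HFD, 3 and 0 in MCD, and 1 and 0 between MCD and HFD. The endothelial markers called when adjusted over the list alone numbered 0 and 0, 3 and 0, and 2 and 0. Without TMM factors endothelial markers numbered 5 higher and 0 lower in MCD and 3 higher and 0 lower between MCD and HFD. For endothelial markers camera gave adjusted p = 0.204, 0.381 and 0.00389, and adjusted p = 0.611, 0.732 and 0.249 with an estimated correlation. The 0 called by edgeR in HFD compare with 0 higher and 3 lower at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by limma-voom, and the median there changed sign without TMM factors. Stab2, a scavenger receptor, was higher in MCD than in HFD by 0.46 ± 0.089 (adjusted p = 0.012), and that list test gave 0.0752 without HFD replicate 2, and 0.116 without HFD replicate 2 and MCD replicate 3. Cholangiocyte and progenitor markers had 0 of 13 members higher and 1 lower in HFD, 3 and 1 in MCD, and 0 and 0 between MCD and HFD. The cholangiocyte markers called when adjusted over the list alone numbered 0 and 1, 3 and 1, and 0 and 0. For cholangiocyte markers camera gave adjusted p = 0.704, 0.114 and 0.00511, and adjusted p = 0.852, 0.534 and 0.258 with an estimated correlation. In HFD their list test pointed down and the median up, and the MCD test passed at 0.0455 without MCD replicate 5, and at 0.0404 without HFD replicate 2 and MCD replicate 3. The 0 cholangiocyte markers called by edgeR between MCD and HFD compare with 3 higher and 0 lower at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by limma-voom, and that list test gave 0.0529 by fry, 0.101 with the covariate for non-unique alignments and 0.12 after thinning. Krt18, a keratin, stood at 0.47 ± 0.15 between MCD and HFD (adjusted p = 0.0925) and was called without HFD replicate 2 (adjusted p = 0.00969). Lymphocyte markers had 0 of 5 members higher and 0 lower in HFD, 0 and 1 in MCD, and 0 and 1 between MCD and HFD. The lymphocyte markers called when adjusted over the list alone numbered 0 and 0, 0 and 1, and 0 and 1. For lymphocyte markers camera gave adjusted p = 0.601, 0.777 and 0.895, and adjusted p = 0.729, 0.826 and 0.901 with an estimated correlation. The 0 lymphocyte markers called by edgeR in HFD compare with 1 higher and 0 lower at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by limma-voom. The lymphocyte median and mean differed in sign in HFD, where the median also changed sign without TMM factors, and between MCD and HFD. Adipose tissue markers had 0 of 5 members higher and 1 lower in HFD, 0 and 0 in MCD, and 1 and 0 between MCD and HFD. The adipose markers called when adjusted over the list alone numbered 1 and 1, 0 and 0, and 1 and 0. For adipose markers camera gave adjusted p = 0.433, 0.837 and 0.233, and adjusted p = 0.602, 0.871 and 0.396 with an estimated correlation. The 0 adipose markers called by edgeR in MCD compare with 1 higher and 0 lower at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by limma-voom. The adipose median and mean differed in sign in HFD and between MCD and HFD, where the median also changed sign without TMM factors. Csf3r, the 1 tested neutrophil marker, rose by 0.97 ± 0.23 in HFD and 1.05 ± 0.22 in MCD, and stood at 0.08 ± 0.20 between MCD and HFD (adjusted p = 0.0128, 0.00205 and 0.87). Cela1, the 1 tested pancreatic marker, changed by -0.73 ± 0.21 and -1.15 ± 0.21, and stood at -0.42 ± 0.21 (adjusted p = 0.0439, 8.20e-04 and 0.278). The HFD call of Cela1 ended without BD replicates 1, 2, 3, 4 or 5, HFD replicates 1, 2, 3 or 5 or MCD replicates 3 or 5 (adjusted p = 0.0583, 0.0673, 0.0641, 0.115, 0.0748, 0.0705, 0.068, 0.0792, 0.0621, 0.0571 and 0.0573 in turn). It also ended without a count filter, without HFD replicate 2 and MCD replicate 3 together, and after thinning (adjusted p = 0.0524, 0.0752 and 0.0667). Both calls of Csf3r ended after thinning, with log2 fold changes of 0.66 and 0.61 (adjusted p = 0.199 and 0.161). Between MCD and HFD Cela1 was called without HFD replicate 2 (adjusted p = 0.0351). The erythroid markers Alas2 and Bpgm were not called in any pair of diets by edgeR (adjusted p at least 0.249, for Bpgm in MCD vs BD, which was called without TMM factors), and these 4 genes were chosen after their values were seen.

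Acute phase genes had 4 of 25 members higher and 0 lower in HFD, 5 and 3 in MCD, and 1 and 2 between MCD and HFD. Adjusted over the list alone, 6 and 0, 7 and 3, and 1 and 2 acute phase genes were called. Without TMM factors 8 and 1 were called in MCD. For acute phase genes camera gave adjusted p = 0.00182, 0.09 and 0.4, and adjusted p = 0.306, 0.596 and 0.81 with an estimated correlation. Steap4, a metalloreductase, rose by 1.08 ± 0.18 in HFD (log2, SE, edgeR adjusted p = 0.0012), and HFD replicate 2 had an acute phase score of 1.3 against -0.0116 to 0.612 in the other HFD libraries. With DESeq2 size factors, or a library size without the 20 most abundant genes, acute phase genes numbered 6 higher and 2 lower in MCD. The MCD test of acute phase genes passed at 0.0106 without HFD replicate 2 and 0.0368 without MCD replicate 1, and at 0.00469 without HFD replicate 2 and MCD replicate 3, and the HFD test gave 0.0557 by fry. Genes of endoplasmic reticulum stress and ATF4 had 3 of 24 members higher and 1 lower in HFD, 5 and 1 in MCD, and 1 and 0 between MCD and HFD. Adjusted over the list alone, 5 and 3, 5 and 1, and 1 and 0 stress genes were called. Without TMM factors 5 and 1 were called in HFD. For stress genes camera gave adjusted p = 0.0326, 0.0201 and 0.358, and adjusted p = 0.28, 0.2 and 0.6 with an estimated correlation. Psat1, of serine synthesis, rose by 2.62 ± 0.30 in HFD and 2.91 ± 0.29 (2.32 after thinning) in MCD (adjusted p = 1.86e-05 and 3.35e-06). The stress list call ended in HFD at 0.103 without BD replicate 1, 0.056 without BD replicate 3 and 0.0515 without HFD replicate 1, and in MCD at 0.0577 without BD replicate 1 and 0.118 without MCD replicate 2. NRF2 targets had 1 of 23 members higher and 8 lower in HFD, 3 and 1 in MCD, and 5 and 0 between MCD and HFD. The NRF2 targets called when adjusted over the list alone numbered 1 and 11, 3 and 1, and 11 and 0. Without TMM factors 8 and 0 were called between MCD and HFD. For NRF2 targets camera gave adjusted p = 1.18e-08, 0.929 and 3.26e-10, and adjusted p = 0.116, 0.971 and 0.106 with an estimated correlation. In MCD their median and mean differ in sign and the median changed sign without TMM factors, and HFD replicate 2 scored -0.0313 against -0.804 to -0.52. The MCD test of NRF2 targets passed at 0.0468 with the covariate. Targets of p53 had 0 of 19 members higher and 0 lower in HFD, 5 and 0 in MCD, and 1 and 0 between MCD and HFD. The p53 targets called when adjusted over the list alone numbered 0 and 0, 7 and 0, and 5 and 0. Without TMM factors p53 targets numbered 3 higher and 0 lower between MCD and HFD. For p53 targets camera gave adjusted p = 0.667, 0.00656 and 4.00e-04, and adjusted p = 0.812, 0.161 and 0.106 with an estimated correlation. Eda2r, a receptor, rose by 2.92 ± 0.51 (3.55 without BD replicate 5 and 2.06 with the covariate for non-unique alignments) in MCD against BD and Btg2, an antiproliferative gene, by 1.07 ± 0.26 against HFD (adjusted p = 5.74e-04 and 0.0354). The 0 p53 targets called by edgeR in HFD compare with 3 higher and 3 lower at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom. Immediate early genes had 0 of 20 members higher and 0 lower in HFD, 9 and 0 in MCD, and 6 and 0 between MCD and HFD. The early genes called when adjusted over the list alone numbered 0 and 0, 9 and 0, and 8 and 0. For early genes camera gave adjusted p = 0.344, 9.97e-06 and 2.87e-08, and adjusted p = 0.812, 0.2 and 0.195 with an estimated correlation. Klf6, a transcription factor, rose by 1.56 ± 0.21 in MCD against BD and 0.99 ± 0.20 against HFD (adjusted p = 7.65e-05 and 0.016). The 0 early genes called by edgeR in HFD compare with 2 higher and 0 lower at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom. Male-biased liver genes had 0 of 24 members higher and 2 lower in HFD, 0 and 8 in MCD, and 0 and 2 between MCD and HFD. The male-biased genes called when adjusted over the list alone numbered 0 and 3, 0 and 11, and 0 and 3. For male-biased genes camera gave adjusted p = 0.201, 4.83e-05 and 1.25e-05, and adjusted p = 0.812, 0.414 and 0.405 with an estimated correlation. Hsd3b2, a steroid dehydrogenase, changed by -0.67 ± 0.11 in MCD against BD (adjusted p = 3.75e-04), and Cyp2u1 fell from 27.3 ± 8.63 CPM in HFD to 13.6 ± 2.59 in MCD (SD, n = 5, adjusted p = 0.0219). The male-biased score was -1.85 in HFD replicate 2, against -0.167 to 0.645 in the other HFD libraries, and the HFD test passed at 0.0202 without BD replicate 3, 0.0128 without HFD replicate 3 and 0.00449 without HFD replicate 4. The male-biased test of MCD against HFD gave 0.18 by fry. With the covariate its direction turned (adjusted p = 0.625), and the MCD test gave 0.357. Female-biased liver genes had 2 of 15 members higher and 1 lower in HFD, 4 and 4 in MCD, and 1 and 2 between MCD and HFD. The female-biased genes called when adjusted over the list alone numbered 2 and 2, 5 and 4, and 2 and 3. For female-biased genes camera gave adjusted p = 0.67, 0.602 and 0.687, and adjusted p = 0.852, 0.863 and 0.88 with an estimated correlation. The MCD test of female-biased genes passed at 0.0415 after thinning. Gluconeogenesis and fasting genes had 1 of 19 members higher and 1 lower in HFD, 1 and 3 in MCD, and 0 and 1 between MCD and HFD. Adjusted over the list alone, 2 and 2, 1 and 3, and 0 and 1 fasting genes were called. Without TMM factors 2 and 3 were called in MCD. For fasting genes camera gave adjusted p = 0.568, 0.16 and 0.19, and adjusted p = 0.812, 0.616 and 0.6 with an estimated correlation. The fasting list passed at 0.0272 without MCD replicate 5 in MCD and at 0.0244 without MCD replicate 5 between MCD and HFD. Plasma proteins of hepatocytes had 0 of 28 members higher and 0 lower in HFD, 0 and 14 in MCD, and 0 and 2 between MCD and HFD. The plasma proteins called when adjusted over the list alone numbered 0 and 0, 0 and 19, and 0 and 8. Without TMM factors plasma proteins numbered 1 higher and 9 lower in MCD. For plasma proteins camera gave adjusted p = 0.0102, 1.98e-06 and 4.59e-05, and adjusted p = 0.485, 0.161 and 0.249 with an estimated correlation. The 0 plasma proteins called by edgeR in HFD compare with 0 higher and 7 lower at an unadjusted p under 0.05, 1 called by DESeq2 and 1 by limma-voom, and that list test gave 0.0725 by fry and 0.0508 without HFD replicate 2 and MCD replicate 3. Serpinc1 stood at -0.26 ± 0.078 in HFD (adjusted p = 0.0534) and was called without MCD replicate 2 (adjusted p = 0.0449), and Fgb, a fibrinogen chain, changed by -0.65 ± 0.15 between MCD and HFD (adjusted p = 0.0296). Between MCD and HFD the call of Btg2 ended without HFD replicates 3, 4 or 5 or MCD replicates 2, 4 or 5 (adjusted p = 0.0851, 0.107, 0.0922, 0.056, 0.0504 and 0.0618 in turn). The call of Cyp2u1 ended without HFD replicates 3, 4 or 5 or MCD replicates 1 or 4 (adjusted p = 0.058, 0.0786, 0.0504, 0.0679 and 0.0632 in turn). The call of Fgb ended without HFD replicates 1, 3 or 4 or MCD replicates 1, 4 or 5 (adjusted p = 0.0583, 0.0851, 0.0952, 0.0856, 0.0748 and 0.0658 in turn), and that of Klf6 without HFD replicate 4 (adjusted p = 0.0586).

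Lists past the camera threshold numbered 18 of 31 for HFD vs BD, 20 for MCD vs BD and 16 for MCD vs HFD (16, 20 and 12 by fry, which tests whether a list's genes move on balance 1 way). In 100 splits of the libraries into groups of the same sizes, the real 1 included, 13, 8 and 18 splits gave as many lists. Another split gave at most 23, 22 and 19 lists, and the median over the other splits was 11, 12 and 11. Chance is therefore not excluded for the number of lists. A single list past the camera threshold with the preset correlation is weak support by itself. For the number of genes called, 1, 1 and 3 of 100 splits gave as many as the real 844, 2610 and 384. Another split gave at most 144, 942 and 887, the 942 from exchanging MCD replicate 3 for BD replicate 5. Chance is excluded at the share of 0.05 for HFD and MCD against BD. For MCD vs HFD it is not, since 2 other splits gave more genes and the share was not corrected over comparisons. Both exchanged HFD replicate 2, for MCD replicate 2 (529 genes) or 3 (887), which bears on its label, left open above. For the overlap of 664 genes, 1 of 100 regroupings gave as many, with at most 4 in another. Regrouping breaks up the diets behind the calls as well, so this does not test overlap beyond the number of calls.

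Of 19 clock genes, 11 were called higher and 4 lower in HFD against BD, 10 and 6 in MCD against BD, and 0 between MCD and HFD by edgeR (0 higher and 2 lower at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom). A general shift of scale in the BD libraries would put the called clock genes on 1 side, but at least 4 were called on each side in HFD vs BD, which argues against it. BD sample numbers lie 66 apart from those of the other diets, so a different time of day or batch of the BD samples may account for the pattern and cannot be told apart from the diet. The diet itself stays open and untested, since a test would need samples of all diets taken at the same recorded hour.

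Of 70 tested P450 and glutathione conjugation genes, 31 were called lower in HFD and 30 in MCD against BD, with medians over the genes called lower of -1.23 and -1.02 on the log2 scale, and over all 70 of -0.385 and -0.32. A lower share of hepatocyte RNA would lower these genes about as much as the 28 plasma protein genes, whose median was -0.144 in HFD (lowest -0.423) and -0.359 in MCD (lowest -0.733), but 23 and 14 of the 70 had a 95% interval below the lowest plasma protein gene, where 1.75 would by chance, which argues against it as the whole cause. It stays open for the 8 and 16 genes called lower whose interval reaches the plasma protein range. Reads lost to near-identical family members stay open: 31 of the 31 members stayed called with the covariate for non-unique alignments, but that measure was about the same in HFD and BD (1.89 and 1.88), so the test could not have removed such a loss and the explanation cannot be told apart. Diet composition other than fat and a batch or time of day of the BD samples stay open and untested.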
